A study of Mus musculus with 12 samples.

How the data were processed

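RNA was measured in 12 libraries of mouse mammary epithelium from female mice. Per the labels, basal and luminal epithelial cells came from floxed Foxp1 controls and from Foxp1 conditional knockouts, which gave 4 groups of 3 biological replicates. Total RNA was taken with an RNeasy kit and libraries were made with the TruSeq RNA v2 protocol for an Illumina HiSeq instrument, per the labels' protocols. CASAVA 1.8.2, featureCounts and the mm10 build are named in the submitters' processing notes. The aligner and the gene annotation are not given in the sources used here. The deposited values are whole-number counts of reads per gene for 27179 Entrez genes, of which 859 have no symbol, with no normalization by the authors. A separate table for each of the 12 libraries was compared with the series table, and 0 values differed. Because the counts are per gene, reads from any exon of Foxp1 enter its count, including reads outside the deleted part.

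Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion, TMM factors and the default expression filter by group, which left 14903 genes holding at least 99.85% of the counts of every library. All 12 libraries entered a model of 4 group means with 8 residual degrees of freedom. Contrasts were basal knockout-labelled against control, luminal knockout-labelled against control, the difference between these effects, and luminal against basal in the controls. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and every adjusted p of a gene below comes from this test unless another is named. Standard errors are the size of the log2 fold change divided by the square root of F. The common biological coefficient of variation was 32.6%. Levels are CPM, library-scaled counts with TMM factors, as mean ± SD over 3 libraries. For a gene with 3 or fewer counts over a group, the ratio of summed counts is given with its exact 95% counting interval, and a group with 0 counts was set to 3 counts over the group. These intervals cover counting error only.

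There were 26 gene lists with 436 distinct genes, written before the data were examined together with the design, the other settings to be tried and the rule for named genes. The 23 lists with at least 4 tested genes were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjusted p-values of lists are Benjamini-Hochberg values over the 23 lists. The Foxp family, adipocyte and red blood cell lists had fewer tested genes and no set test. Named genes were Foxp1 in every library and, per knockout comparison, up to 12 rises and 12 falls with the largest folds. These had to be called, have an average log2 CPM of at least 1 and have groups that do not overlap, and predicted genes without a name were left out. The rule also took the 10 interaction genes with the lowest p, the 4 called members with the largest fold in each lineage list, and up to 4 called members per list, or up to 2 with the lowest p where none was called. A fixed set including Tspan8, Lgr5, Mki67, Esr1, Pgr and the keratins was always given. Of the genes the rule took, 2 are not reported here; they stay in the counts of lists and of named genes. Gene positions are from RefSeq on GRCm38, the mm10 assembly, matched by gene number for 25275 genes.

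Replicate numbers are shared between groups, so pairing was checked by correlating each library's deviations from its group mean. Between luminal knockout-labelled and control libraries of the same number the correlations were 0.36, 0.30 and 0.53, and between control luminal and basal libraries they were 0.31, 0.42 and 0.47. The numbers were therefore taken to pair the libraries in those comparisons, and the fit with replicate number as a block is printed beside them where it moves the count. No replicates agreed within sampling noise, since the chi-square per degree of freedom was between 12.6 and 148 for every pair within a group. Alternatives were other scalings, filters and tools (DESeq2 1.42.0, limma-voom), fewer libraries in the fit, the replicate block and leaving out each library.

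The edgeR step was tested on simulated data with gene means pooled within each cell type and the real library sizes and dispersions. Each library was drawn independently, and the changed genes were picked above a floor of mean counts. Deviations shared by libraries of the same number were not simulated, so the false calls below do not bound those in the real data. In the simulated basal comparison of 14715 genes it called 78 of 100 genes changed 4-fold and 6 of 100 changed 2-fold, with 1 false call. In the simulated luminal comparison of 14738 genes it called 73 of 100 at 4-fold and 16 of 100 at 2-fold, with 1 false call. Most changes near 2-fold would therefore be missed at this depth and replication. Prp2, Prh1, Mup5, Scgb2b26 and Igkc belong to families with similar copies, whose reads the counting could have shared out, and their values are uncertain. The library kit does not mark strand, so overlapping genes on opposite strands cannot be told apart.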

Results

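Gene expression was profiled in basal and luminal epithelial cells of the mouse mammary gland. Foxp1, a forkhead transcription factor, was floxed in control mice and conditionally deleted in the mammary gland of the knockouts, per the labels. Each of the 4 groups had 3 libraries. Total counts were 9769361 to 11133908 per library, except 15449513 in luminal knockout replicate 3. The first principal component, with 63.5% of the variance, separated luminal from basal libraries.

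Foxp1 (Entrez 108655, GRCm38 chromosome 6, 98925342 to 99522746) was read first, because it is the targeted gene. In basal cells it stood at 221, 213 and 160 CPM in control replicates 1, 2 and 3, and at 212, 193 and 284 CPM in the knockout-labelled replicates. In luminal cells it stood at 82.3, 62.0 and 78.2 CPM in controls, and at 161, 150 and 155 CPM in the knockout-labelled replicates. Foxp1 counts rose in the luminal knockout-labelled libraries by a log2 fold of 1.07 (SE 0.19, adjusted p = 0.0161), and the basal log2 fold was 0.22 (SE 0.19, adjusted p = 0.926). The basal and luminal folds were not called different (log2 difference -0.85, SE 0.27, adjusted p = 0.262). The luminal call was lost without luminal control replicate 2 (adjusted p = 0.0746), knockout replicate 2 (0.0524) or knockout replicate 3 (0.054). The gene-level count goes against the knockout label, but it includes reads outside the deleted exons. It is therefore only a partial check and cannot decide whether the deletion took place. For this reason the libraries are called knockout-labelled throughout, and every direction below rests on the labels. Among its relatives, Foxp4 had log2 folds of 0.33 in basal and -0.25 in luminal cells, and Foxp2 of 2.76 and 1.10, none of them called.

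**Figure D1:**
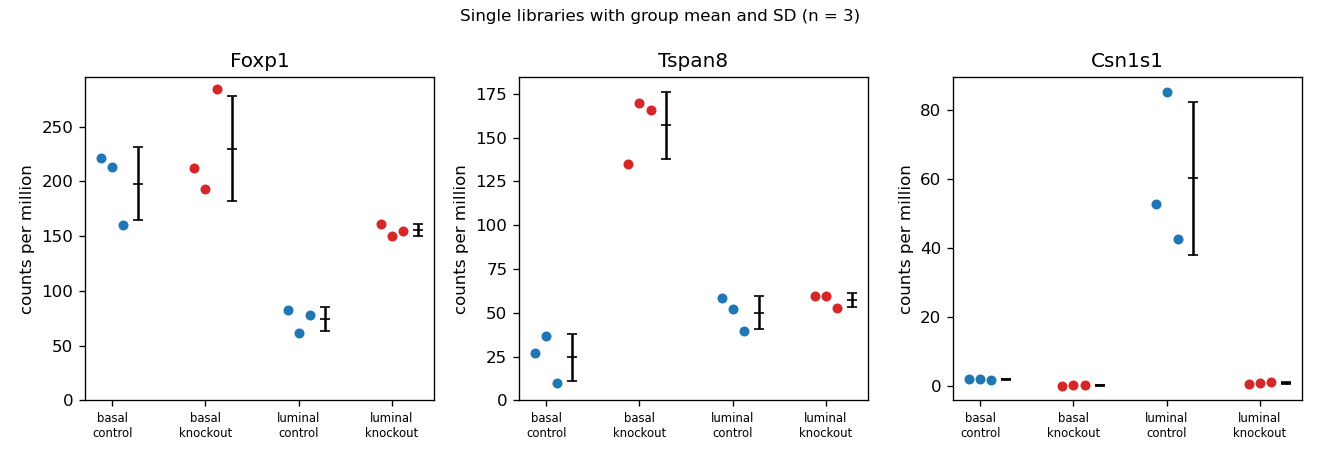
CPM (library-scaled counts) of Foxp1, Tspan8 and Csn1s1 in each of the 12 libraries (points; blue control, red knockout-labelled), with the group mean and SD (n = 3) in black on linear axes. Foxp1 is at 62.0 to 82.3 CPM in luminal controls and 150 to 161 CPM in luminal knockout-labelled libraries, and all basal knockout-labelled libraries hold more Tspan8 than any basal control.

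The controls were compared first between cell types, to see what the sorted fractions held. Genes of contractile myoepithelium were far higher in basal cells: Acta2, smooth muscle actin, was at 3756 ± 2183 CPM in basal and 18.4 ± 5.82 CPM in luminal controls (log2 fold -7.67, SE 0.64, adjusted p = 9.99e-06, n = 3). Actg2, Myh11 and Mylk had log2 folds of -8.15, -7.49 and -6.92. All 20 basal and myoepithelial markers were lower in luminal cells, over all genes and adjusted over the list alone (camera adjusted p = 2.12e-15; adjusted p = 0.0574 with an estimated correlation). Among luminal progenitor markers 16 of 18 were higher in luminal cells and 17 adjusted over the list alone, led by Cxcl15, the receptor Kit (log2 fold 5.34, SE 0.53), Wfdc18 and the transcription factor Elf5 (5.04, SE 0.54). Hormone-sensing markers were higher for 13 of 19 and lower for 1, or 15 and 1 adjusted over the list alone, with Tnfsf11, the cytokine RANKL, at a log2 fold of 6.65 (SE 0.70), Calca at 6.22, the prolactin receptor Prlr at 5.79 and Fgb at 5.69. Pan-luminal markers were higher for 11 of 14, or 12 adjusted over the list alone, among them Krt19, Cldn3, Krt18 and Cldn7 (camera adjusted p = 2.03e-07; adjusted p = 0.0615 with an estimated correlation). Milk genes were higher for 13 of 15 (14 higher and 1 lower adjusted over the list alone), and their call held with an estimated correlation (adjusted p = 0.00519), as did those of progenitor (0.00666) and hormone-sensing markers (0.0297). Basement membrane and matrix genes were lower for 23 of 26, the same count as adjusted over the list alone, and Wnt genes for 17 of 25 with 2 higher, or 17 and 5 adjusted over the list alone. Both calls were lost at adjusted p = 0.0615 with an estimated correlation. Mammary stem cell genes were lower for 9 of 17 and higher for 3 (10 and 3 adjusted over the list alone), again with adjusted p = 0.0615 with an estimated correlation. Fibroblast and pericyte markers were lower in luminal cells for 5 of 16 and 5 of 8, or 5 and 6 adjusted over the list alone, and 1 of each was higher on both counts (adjusted p = 0.744 and adjusted p = 0.201 with an estimated correlation). In all, 4942 genes were called, 2435 higher and 2507 lower in luminal cells, and 6476 with replicate number as a block.

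In basal cells the knockout-labelled libraries held more transcripts of a small set of genes. Tspan8, a tetraspanin on the list of mammary stem cell genes (Entrez 216350, chromosome 10, 115816817 to 115849893), rose from 24.6 ± 13.5 to 157 ± 19.3 CPM (log2 fold 2.67, SE 0.37, adjusted p = 0.00933, n = 3). Agouti, the coat colour signalling gene with the symbol a (chromosome 2, 154950599 to 155051012), rose from 0.28 ± 0.18 to 146 ± 18.3 CPM, and Fmn2, a formin (chromosome 1), had 2 control and 775 knockout-labelled counts, a ratio of 406 with a counting interval of 112 to 3360. Trf, transferrin, rose from 554 ± 217 to 3633 ± 179 CPM. Slit2, a secreted axon guidance ligand, fell from 45.2 ± 5.37 to 11.3 ± 1.76 CPM (log2 fold -1.99, SE 0.20, adjusted p = 0.00143). In all, edgeR called 100 genes, 91 higher and 9 lower, and 12.4% of tested genes had groups that do not overlap, against 10% by chance.

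The other largest rises in basal cells came in several kinds of gene. The glutamate receptor subunit Gria4 rose by a log2 fold of 4.72 (SE 0.63, adjusted p = 0.00933), the somatostatin receptor Sstr1 by 3.60 (SE 0.40), and the neuropeptide receptor Adcyap1r1 by 3.71 (SE 0.64). Cntnap4, Atp13a5 and Tmem229a had log2 folds of 3.86, 5.02 and 5.10. Plac9a had 3 control and 188 knockout-labelled counts, a ratio of 65.6 with a counting interval of 22.1 to 321. Thbs4, Lpl and the vessel growth factor Angpt1 rose by log2 folds of 3.61, 3.48 and 3.54. Fibroblast markers also had a higher median in these libraries, as given below. Whether the rises of single genes came with more stromal cells in the sorted fraction was not tested. Falls were seen in the kinesin Kif1a (log2 fold -2.18, SE 0.31), the calcium channel Cacna1g (-1.50, SE 0.29), Sorcs1 (-2.93), Gpalpp1 (2.01-fold lower), Smr3a, a salivary gland transcript (-5.89, SE 1.02), and the casein Csn1s1 (-3.41, SE 0.57).

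By list, markers of fibroblasts moved most in basal cells. Their median log2 fold was 2.07, 2 of 16 rose (Pdgfra, log2 fold 2.41, SE 0.36; Dpp4, 2.85, SE 0.53) and 12 rose adjusted over the list alone (camera adjusted p = 4.43e-11; adjusted p = 0.152 with an estimated correlation). Pericyte markers had 0 of 8 called and 2 higher adjusted over the list alone, with Des at 1.91 and Abcc9 at 1.71 (camera adjusted p = 0.00498; adjusted p = 0.137 with an estimated correlation). Among interferon response genes Cxcl10 rose (1.69, SE 0.33), 1 of 22, with 9 higher adjusted over the list alone (camera adjusted p = 2.81e-11; adjusted p = 0.137 with an estimated correlation). Hormone-sensing markers had 2 of 19 higher, the pioneer factor Foxa1 (2.01, SE 0.29) and Sytl2 (2.73, SE 0.51), and 4 adjusted over the list alone (adjusted p = 0.137 with an estimated correlation). Sytl2 was also the 1 of 18 hormone response genes called, over all genes and adjusted over the list alone. Pan-luminal markers had 0 of 14 called and 2 adjusted over the list alone, with Krt19 at 1.59 and Cldn3 at 0.93 (camera adjusted p = 0.00319; adjusted p = 0.248 with an estimated correlation). Tspan8 was the 1 of 17 stem cell genes called, with 2 adjusted over the list alone (camera adjusted p = 0.0386; adjusted p = 0.248 with an estimated correlation), while Lgr5 stayed at a log2 fold of -0.04 (SE 0.41).

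Cell cycle inhibitor and quiescence genes had 0 of 19 called on either count adjusted over the list alone or over all genes, with Rb1 at 0.80 and Gas1 at 1.04, Cdkn1a at 0.55, Cdkn1b at 0.26 and Cdkn1c at 0.34 (camera adjusted p = 0.00327; adjusted p = 0.137 with an estimated correlation). G2/M genes had 0 of 24 called over all genes and adjusted over the list alone and a median of -0.65, with Nek2 at -0.92, Cenpe at -0.87 and Mki67 at -0.70 (camera adjusted p = 0.00435; adjusted p = 0.775 with an estimated correlation). Mki67 was at 167 CPM in basal control replicate 3 against 55.6 and 44.0 CPM in the other controls, and that list's call was lost without that library (camera adjusted p = 0.703). Notch genes had 0 of 17 called and 1 adjusted over the list alone, with Notch1 at 0.84 and Heyl at 1.11 (adjusted p = 0.137 with an estimated correlation). Growth factor genes had 0 of 26 called, and 2 higher and 1 lower adjusted over the list alone, with Fgf10 at 4.90 and Ereg at -2.20 (adjusted p = 0.137 with an estimated correlation). Immediate early genes (Ier3 at 0.47, Hspb1 at 0.31) and NF-kB genes (Cxcl1 at 1.40, Nfkbia at 0.60) had 0 of 20 called each, with 0 and 1 adjusted over the list alone, and both camera calls were lost (adjusted p = 0.53 and adjusted p = 0.32 with an estimated correlation). T and B cell markers had a median of -0.80 over 5 tested genes, with 0 called and 1 lower adjusted over the list alone, Igkc at -2.81 and Cd79a at -0.80 (adjusted p = 0.137 with an estimated correlation).

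The remaining lists passed no camera test in basal cells. Basal markers had 0 of 20 called over all genes and adjusted over the list alone, with Dkk3 at 0.72, Cxcl14 at 0.87, Krt5 at -0.26 and Krt14 at 0.38. Progenitor markers had 1 of 18 higher (Trf), and 1 adjusted over the list alone. Signs disagreed in some lists: the median was -0.01 and the mean -0.10 for progenitor markers although camera's direction was up, and basal markers and matrix genes had medians of -0.015 and -0.086 beside means of 0.075 and 0.033. Milk genes had Csn1s1 lower, with 3 higher and 3 lower adjusted over the list alone, and a median of 0.17 beside a mean of -0.15. Among Wnt genes the secreted antagonist Sfrp1 rose (1.70, SE 0.23), 1 of 25, with 2 higher and 2 lower adjusted over the list alone. Matrix genes (Fn1 at 2.34, Lama1 at -1.25), S phase genes (E2f8 at -0.80, Cdt1 at 0.45), macrophage markers (Cd14 at 0.62, Cd74 at -0.84), lipid synthesis genes (Scd1 at 1.47, Srebf1 at 0.66) and endothelial markers (Vwf at -1.07, Egfl7 at 0.98) had 0 called, with 0, 0, 0, 1 and 1 adjusted over the list alone. Adipocyte genes Pparg and Lipe were at 2.40 and 1.10 and the red cell gene Alas2 at -0.41, and Ccnd1, Esr1, Pgr, Krt8 and Krt18 were at -0.83, -0.63, 0.26, 0.39 and 0.88, none called. The basal count fell to 17 without control replicate 1, 35 without knockout replicate 1, 28 without control or knockout replicate 2 and 49 without knockout replicate 3, and Tspan8 lost its call without control replicate 1 (adjusted p = 0.0654), while Smr3a and Csn1s1 lost theirs on leaving out any single basal library other than control replicate 3. DESeq2 called 417 genes, and scaling by library size alone 59.

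In luminal cells the knockout-labelled libraries differed in more genes. Col8a1, a short-chain collagen (chromosome 16, 57624256 to 57754737), fell from 103 ± 34.6 to 2.91 ± 0.67 CPM (log2 fold -5.14, SE 0.29, adjusted p = 1.54e-05, n = 3). Csn1s1, a casein of milk (chromosome 5, 87666208 to 87682578), fell from 60.2 ± 22.3 to 0.85 ± 0.27 CPM (log2 fold -6.10, SE 0.44), and Csn2 fell with a log2 fold of -5.47 (SE 0.75). Tnfsf11 fell from 26.6 ± 11.9 to 0.71 ± 0.36 CPM and the growth factor Igf2 from 61.9 ± 45.5 to 1.52 ± 0.85 CPM. Il1rl1, the IL-33 receptor, rose from 4.15 ± 3.66 to 642 ± 471 CPM (log2 fold 7.28, SE 1.07, adjusted p = 0.00744), and agouti rose from 0.19 ± 0.24 to 48.7 ± 4.38 CPM. In all, 451 genes were called, 329 higher and 122 lower, and 25.4% had groups that do not overlap, against 10% by chance. With replicate number as a block 932 genes were called, 625 higher and 307 lower, with 414 of the 451 among them. Luminal genes given below as not called rest on the fit without that block.

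Further rises included Cartpt, a neuropeptide precursor (log2 fold 8.17, SE 0.99), Pcp4 (6.25, SE 0.90), the cornified envelope protein Ivl (6.01, SE 1.31) and the ion channel Asic2 (5.83, SE 0.93). Prp2 had 1 control and 979 knockout-labelled counts, a ratio of 851 with a counting interval of 152 to 33600, and Scgb2b26 had 1 and 399, a ratio of 347 with an interval of 61.9 to 13700. Slc5a11 had 2 and 528 counts, a ratio of 229 with an interval of 63.2 to 1900, and Efcab1, with 0 control counts, was at least 24.6-fold higher. Prh1 and Mup5 rose by log2 folds of 9.23 and 6.21, with reads that related copies could share. Beyond the caseins, falls included Smr3a (-9.47, SE 1.18), Zfp979 (-5.84), Rspo1, a Wnt agonist (-3.70, SE 0.82), Rbm24 (-3.62), St6gal1 (-3.60), Fam180a (-3.46) and Grik3 (-3.09). Salivary RNA was present in these libraries: Bpifa2, a salivary transcript, took 0.636% to 6.05% of counts in luminal controls. It took 1.61% to 6.7% in luminal knockout-labelled libraries. Whether the rises above, such as those of Prp2, Prh1, Mup5 and Scgb2b26, came with such RNA was not tested. Rn45s, ribosomal RNA, took 3.68% of counts in luminal control replicate 2.

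Of 22 interferon response genes 5 were called higher in luminal cells and 15 rose adjusted over the list alone, with a median log2 fold of 1.03. Among them were Usp18 (2.54, SE 0.33), Bst2 (1.04, SE 0.21) and Cxcl10 (1.42, SE 0.32), and camera gave adjusted p = 9.02e-10 (adjusted p = 0.137 with an estimated correlation). Luminal progenitor markers had 3 of 18 lower, Csn2, Rspo1 and Sox10 (-1.05, SE 0.25), and 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00263; adjusted p = 0.137 with an estimated correlation). Milk genes had 2 of 15 lower, Csn1s1 and Csn2, and 6 adjusted over the list alone (camera adjusted p = 0.00263; adjusted p = 0.116 with an estimated correlation). Csn2, Csn3 and Lalba are on both lists, so these list calls are not separate. Immediate early genes had 0 of 20 called and 0 adjusted over the list alone, with Egr3 at -1.56 and Hspa1a at -0.99, and endothelial markers had 0 of 14 and 0 adjusted over the list alone, with Pecam1 at -1.33 and Esam at -1.16. Both had a camera adjusted p of 0.0181 and adjusted p = 0.788 with an estimated correlation.

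Hormone-sensing markers moved both ways in luminal cells. Tnfsf11, the transcriptional regulator Cited1 (-2.81, SE 0.36) and Fgb (-2.90, SE 0.62) fell, Fxyd2 (1.97, SE 0.38) and Sytl2 (2.08, SE 0.45) rose, and 8 were higher and 4 lower adjusted over the list alone. Esr1 and Pgr, the oestrogen and progesterone receptors, were at 1.12 (SE 0.72) and 1.71 (SE 0.58), not called. In the hormone response list Greb1 rose (5.18, SE 1.25, adjusted p = 0.05 after rounding), with Sytl2 higher and Tnfsf11 lower, and 4 were higher and 2 lower adjusted over the list alone. Basal markers had Dkk3 (2.80, SE 0.35) and the basal transcription factor Trp63 (2.80, SE 0.58) higher, 2 of 20, with 7 higher and 1 lower adjusted over the list alone. The cadherin Cdh3 (2.94, SE 0.44), the Notch ligand Jag1 (1.56, SE 0.30) and the hemidesmosome collagen Col17a1 (4-fold, adjusted p = 0.0466) were each the 1 called member of the stem cell, Notch and matrix lists. Adjusted over the list alone these had 1 higher and 2 lower, 1 higher, and 2 higher. Among Wnt genes Dkk3 rose and Wnt5b fell (-1.60, SE 0.29), with 1 higher and 5 lower adjusted over the list alone. Saa1, an acute phase protein, rose (3.38, SE 0.78) as the 1 called NF-kB gene, also on the count adjusted over the list alone. None of the lists in this paragraph passed camera, and hormone-sensing and hormone response genes had medians of 0.20 and -0.007 beside means of -0.10 and 0.083.

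Of the other lists in luminal cells, 0 genes were called. Pan-luminal markers (Muc1 at -1.19, Krt19 at 0.60), S phase genes (Slbp at -0.42, Rrm2 at 0.62), G2/M genes (Kif20b at -0.74, Aurka at -0.37), inhibitor and quiescence genes (Cdkn1c at -0.88, Foxo3 at -0.59), lipid synthesis genes (Me1 at 0.72), fibroblast markers (Pdgfrb at -1.81, Dcn at 1.01), pericyte markers (Abcc9 at 1.85) and T and B cell markers (Cd4 at -2.20; Igkc with 19 control and 2 knockout-labelled counts, 10.9-fold lower with a counting interval of 2.64 to 96.8) also had 0 adjusted over the list alone. Growth factor genes (Egfr at -0.67, Spry1 at 1.25) had 1 higher and 1 lower, and macrophage markers (Cd74 at -1.80, Csf1r at 2.16) 1 higher and 2 lower, adjusted over the list alone. Fabp4 and Pparg of adipocytes were at -2.22 and 0.37 and Alas2 at -1.08. Tspan8 was at 0.19 (SE 0.35), Lgr5 at -0.36, Cdkn1a at 0.91, Cdkn1b at -0.39, Mki67 at -0.44, Ccnd1 at -0.07, Krt5 at 0.22, Krt14 at 1.40, Krt8 at 0.29 and Krt18 at 0.49, none called. The luminal count fell to 129 without control replicate 1, 127 without control replicate 2, 142 without knockout replicate 2 and 168 without knockout replicate 3. DESeq2 called 1089 genes, and a fit of the 6 luminal libraries alone 199.

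**Figure D2:**
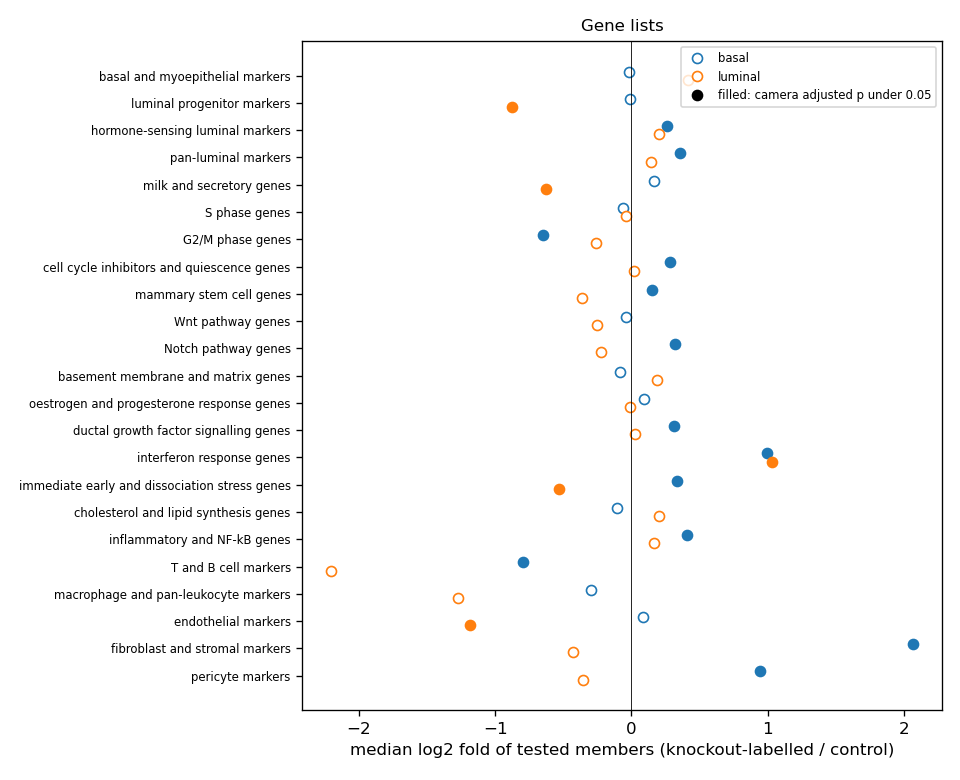
Median log2 fold (knockout-labelled over control) of the tested members of each of 23 gene lists, in basal (blue) and luminal (orange) cells; filled points have a camera adjusted p under 0.05 at the preset correlation. The fibroblast list has a basal median of 2.07 and a luminal median of -0.43, and 0 lists pass with an estimated correlation.

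Both cell types shared some calls. Among genes called in both, 17 were higher in both, against 2.01 for independent lists (Fisher's exact test, two-sided, p = 1.22e-11), among them agouti, Fmn2, Gria4, Cntnap4, Atp13a5, Sytl2 and Cxcl10. Kif1a, Csn1s1 and Smr3a were the 3 lower in both, against 0.0737 (p = 4.34e-05, exact). Csn1s1 and Smr3a stood at 1.87 and 435 CPM in basal controls against 60.2 and 13290 CPM in luminal controls. For Kif1a these levels were 78.09 and 7.025 CPM. The basal falls of Csn1s1 and Smr3a may come with luminal or salivary RNA in the basal libraries. Less salivary RNA was weighed for basal Smr3a below and stays open, and luminal RNA was not tested. Both falls may therefore repeat the luminal ones, although the exact test above counts them as separate. Ntn1, Angpt1 and Lpar1, the last named after its values were seen, were higher in basal and lower in luminal cells. These 3 stood against 0.745 for independent lists (Fisher's exact test, p = 0.0387), and 0 genes went the opposite way, against 0.199. With DESeq2 the counts were 16 against 8.86 (Fisher's exact test, p = 0.0229) and 2 against 3.07. With the replicate block they were 4 against 2.62 (Fisher's exact test, p = 0.337) and 1 against 0.839. Basal and luminal cells with the same number may come from the same animals, so the overlap is not that of independent mice.

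**Figure D3:**
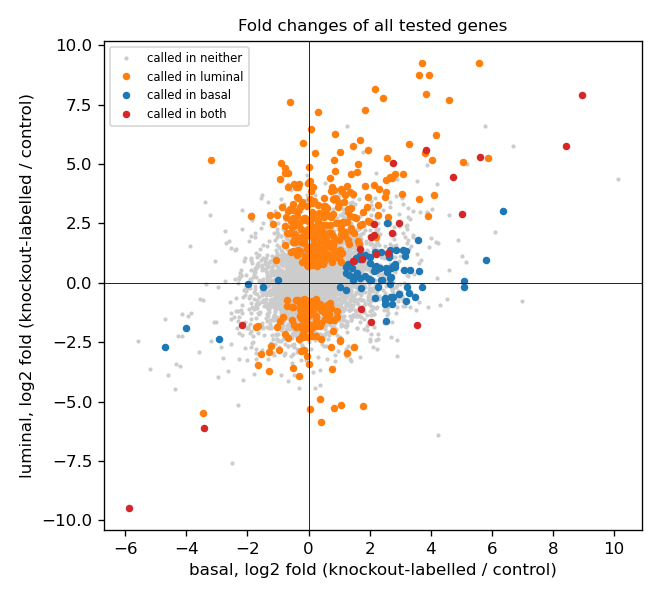
Log2 fold change of each of 14903 tested genes in basal (x) and luminal (y) cells, knockout-labelled over control; grey points are called in neither, and coloured points in luminal, basal or both. The 20 genes called in the same direction lie in the upper right (17) and lower left (3) quadrants.

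A test of the difference between the basal and luminal effects called 41 genes, 27 with a higher and 14 with a lower log2 fold in basal cells. With replicate number as a block 87 were called, 30 of the 41 among them. That block joined same-numbered libraries within each cell type, also the basal ones, which were not taken as paired. Pairing between basal and luminal libraries was not modelled. Knockout-labelled basal and luminal libraries of the same number correlated at 0.087, 0.42 and 0.42. Angpt1 went from 2.40 ± 0.46 to 28.04 ± 6.51 CPM in basal and from 12.5 ± 5.40 to 3.66 ± 1.004 CPM in luminal cells (difference 5.33, SE 0.50, adjusted p = 0.00184, n = 3). Ntn1, the guidance cue netrin, had a difference of 2.81 (SE 0.33), and Robo2, a receptor for Slit ligands, of -5.33 (SE 0.57), with 1.11 ± 0.38 CPM in luminal controls and 23.5 ± 4.64 CPM in luminal knockout-labelled libraries. Col8a1, Adcy5, Tmtc1 and Pamr1 had differences of 6.19, 4.20, 3.48 and 3.63, and Cyfip2, Apcdd1 and the calcium release channel Ryr3 of -5.22, -2.88 and -8.37. All 10 of these genes were called in every alternative run. Whether stromal cells in the basal fraction enter the differences of these or other called genes was not tested. The camera test called 9 lists, each with higher signed changes in basal cells, and 0 with an estimated correlation. Fibroblast markers had a median difference of 2.34 (0 of 16 called, 5 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation) and milk genes of 1.31 (0 of 15 called, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0714 with an estimated correlation). The count of 41 ranged from 10 without luminal knockout replicate 2 to 86 without luminal control replicate 3, and DESeq2 called 356.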

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

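The tests of salivary RNA, progenitor cells, the chromosome 5 stretch, the share of basal cells, the positions of shared genes and mislabelling, and the count of splits by pairs parted, were chosen after the results were seen; the second fibroblast list and the regroupings of libraries were set before theirs.

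Genes were picked out here because the basal and luminal effects differed in the interaction test of edgeR (basal minus luminal, log2). Beyond the genes named with their differences in the report (Col8a1 6.19, Angpt1 5.33, Robo2 -5.33, Cyfip2 -5.22, Adcy5 4.20, Ntn1 2.81, Apcdd1 -2.88, Tmtc1 3.48, Ryr3 -8.37, Pamr1 3.63), the differences were 5.03 for Tmem229a, 4.07 for Lpl, -1.95 for Slit2, 6.24 for Zfp979, 5.34 for Igf2, 6.08 for Tnfsf11 and 4.37 for Rbm24. Efcab1 had -8.21, a fitted value set by its 0 counts in luminal controls. Lists whose signed log2 change was higher in basal than in luminal cells had camera adjusted p of 0.000567 for progenitor markers and for milk genes, 2.17e-05 for immediate early genes, 0.0148 for endothelial markers and 1.07e-07 for fibroblast markers. The value was 0.0249 for quiescence genes, stem cell genes, Notch genes and pericyte markers. With an estimated correlation 0 of these calls held.

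Regrouping the libraries gave 3 of 100 drawn splits with at least 41 interaction genes, the real split included, and another split gave 203. That draw was extended after 60 splits had been run, of which 3 were as large, a share of 0.05; the share over 100 is 0.03. The extension was made after the first share was seen and it moved the share across 0.05, so chance is not treated as excluded. The splits were drawn without regard to replicate number, although the numbers pair the luminal libraries: of the 46 drawn splits that part all 3 luminal pairs, as the real one does, 3 were as large, a share of 0.065, and the highest among the rest was 24. Both larger splits kept the luminal groups whole, with their control and knockout labels exchanged, and mixed the basal ones. The real luminal difference therefore enters these counts with its sign turned. For this reason the shares do not measure chance alone. For the basal, luminal and lineage comparisons only 10 splits exist, too few for a share under 0.05. The real split was the 1 split as large in each, with 100, 451 and 4942 genes, and the highest other splits gave 0, 1 and 0. Among the 4 splits that part all 3 pairs the highest other was 0 in the luminal and 0 in the lineage comparison.

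Fibroblast markers had a higher median in the basal knockout-labelled libraries, with 2 of 16 called and the list's call lost with an estimated correlation (adjusted p = 0.152). More stromal cells in the sorted fraction may account for this: a second fibroblast list had a median log2 fold of 1.90, although 0 of its 13 genes were called. A lower share of basal cells would raise every other type alike. The endothelial median was 0.08 beside the fibroblast median of 2.07. Pericyte, pan-luminal and hormone-sensing markers had medians of 0.94, 0.35 and 0.26. Progenitor, macrophage, and T and B cell markers had -0.01, -0.30 and -0.80, and basal markers -0.015. A rise of all types alike is argued against by these values. A smaller fall in the share of basal cells stays open. A change of expression in basal cells themselves stays open.

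Smr3a and 2 of 15 milk genes were called lower in the luminal knockout-labelled libraries; 4 of the 15 lay above 0, and the list's call was lost with an estimated correlation (adjusted p = 0.116). An even loss of salivary RNA is argued against for luminal Smr3a, because the lowest control ratio of Smr3a to Bpifa2 was 216 times the highest knockout-labelled ratio. A changed mix of salivary RNA was not tested and stays open. Amy1, another salivary transcript, took 2.21%, 0.213% and 1.32% of counts in luminal controls, beside 6.05%, 0.636% and 3.12% for Bpifa2. In luminal knockout-labelled libraries Amy1 took 1.06%, 0.404% and 0.138%, beside 6.7%, 2% and 1.61% for Bpifa2. In basal cells the Smr3a to Bpifa2 ratios were 0.101, 0.00128 and 0.00983 in knockout-labelled replicates 1, 2 and 3 against 0.287 to 0.406 in controls. Replicate 2 had 47 Smr3a beside 36597 Bpifa2 counts. All 3 lie below the controls, but the factor was 2.85, short of the bound set because of replicate 1, so the explanation stays open there. The single test over both cell types left it open too, and it was parted by cell type after that was seen. Fewer progenitor cells could account for the milk genes as a list. Progenitor markers off the milk list had a median of -0.73 against -0.62 for milk genes. However, these markers ranged from -3.7 to 1.85 with 2 of 15 called, so they did not all fall. Csn1s1 at -6.10 lies far below both medians. A linked chromosome 5 stretch cannot be told apart from fewer progenitor cells. Milk genes on other chromosomes had a median of -0.53, between the bounds set for either outcome. Those on chromosome 5 had a median of -2.02 with 2 of 5 called, against 0 of 10 on the others, but these 2 are Csn1s1 and Csn2, the genes to be explained, so this decides nothing.

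The 20 genes called the same way in both cell types, with agouti and Fmn2 at the top, were weighed for linkage and mislabelling. A single linked chromosome stretch from another strain is argued against for 17 of them as a set, which lie on 13 chromosomes with at most 3 on any one. Some of the 17 lie on the same chromosome: Nqo1 and Cntnap4 start at 107388225 and 112569798 on chromosome 8. Gm12250 and Pitpnm3 start at 58183843 and 72047528 on chromosome 11. Nqo1, Gm12250 and Pitpnm3 are named here after their values were seen. Smaller stretches holding such genes were not tested and stay open. Of the 20, 0 lie on the chromosome of Foxp1. Of the 32 tested genes near agouti and the 8 near Fmn2, 0 were called. These uncalled neighbours decide nothing about a stretch around either gene, because most changes near 2-fold would be missed. A mislabelled sample cannot be told apart: the lowest knockout-labelled CPM of agouti and Fmn2 was at least 19.6 times the highest control in each cell type, but these genes were picked because they part the labelled groups, so the bound set for them excludes nothing, and it says nothing about exchanged group labels. Both control replicate 3 libraries also lay with the knockout-labelled ones on the second principal component. For Csn1s1, Smr3a and Cxcl10, which lies 4.3 Mb from Smr3a, a linked stretch cannot be told apart from an effect of the genotype: Csn1s1 and Smr3a were the 1 pair within 1 Mb, where random sets of 20 genes had a median of 0 and a 95th percentile of 1. A difference in strain background at several places was not tested and could act on single genes such as agouti.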

How the results depend on the processing

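Leaving out the 4 libraries of number 3 together was chosen after seeing the data; the other alternatives were planned. The cause of these shifts was not tested, beyond fewer libraries in the fits that leave some out. Basal calls (100) became 59 with library size alone, 417 with DESeq2, 1149 with limma-voom sample weights, 151 in the 6 basal libraries, 268 without the number 3 libraries and 17 to 122 with a library left out. Luminal calls (451) became 1089 with DESeq2, 1487 with sample weights, 199 in the 6 luminal libraries, 703 without number 3, 932 with the replicate block and 127 to 589 with a library left out. Interaction calls (41) became 356 with DESeq2, 22 with limma-voom, 424 with sample weights, 87 with the block and 10 to 86 with a library left out. Lineage calls (4942) became 7466 with sample weights and 3533 to 5211 with a library left out. The block gave 147 basal and 6476 lineage calls. Basal knockout-labelled and control libraries of the same number correlated at -0.087, 0.36 and 0.13, and 3 of 6 correlated best with their own number, so they were not taken as paired. Shared rises (17) became 79, 33 and 268, and shared falls (3) 11, 6 and 85, with DESeq2, the block and an unadjusted p under 0.05. Camera calls of lists in basal (13), luminal (5) and interaction (9) tests each became 0 with an estimated correlation. The fry test gave 5 in basal, 4 in luminal and 2 in interaction tests, and it kept 3 of the 5 luminal camera calls. These were milk genes (fry adjusted p = 6.25e-05), progenitor markers (fry adjusted p = 0.00785) and interferon genes (fry adjusted p = 0.00785). Leaving out a library gave 5 to 9 in luminal and 8 to 15 in interaction tests. The lists were not the same: 4 of 13 basal calls (fibroblast, interferon, quiescence, T and B cell), 3 of 5 luminal (interferon, progenitor, milk) and 4 of 9 interaction calls (progenitor, milk, immediate early, fibroblast) were kept whichever library was left out. Calls were lost without basal control or knockout replicate 2 or 3 in basal, luminal knockout 1 or 3 or control 2 or 3 in luminal, and basal control 1, 2 or 3, basal knockout 2 or 3, luminal knockout 1 or luminal control 2 or 3 in interaction tests. S phase genes in luminal cells had camera adjusted p = 0.966, and 0.0323 in the opposite direction without luminal control replicate 3. Luminal Foxp1 ranged from 0.95 to 1.16 and basal Foxp1 from 0.04 to 0.33 with a library left out. Of the named called genes, 21 of 27 basal and 22 of 42 luminal ones lost their call when some library was left out, and 0 reversed. Under some other planned setting 10 basal and 15 luminal ones lost it, 6 and 1 of them with the replicate block. Of the named genes not called, 19 basal and 18 luminal ones gained a call in some planned run.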

Other observations

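Of 20 tested genes of axon guidance, a group chosen after the interaction genes were seen, 5 had a called difference between the cell types, 1 (Ntn1) was called in opposite directions and 10 had the same sign in both. Ntn1 rose in basal cells (log2 fold 1.72, SE 0.24, adjusted p = 0.00933, edgeR) and fell in luminal cells (-1.09, SE 0.23, adjusted p = 0.0274). Robo1 rose in luminal cells (0.95, SE 0.23, adjusted p = 0.0494), where Robo2 rose by 4.38 (SE 0.44, adjusted p = 0.000812), and the differences between the cell types were -2.02 for Robo1 and -5.33 for Robo2. Slit2 fell in basal cells (-1.99) and stood at -0.05 in luminal cells, and its difference of -1.95 was called (adjusted p = 0.026). Plxnd1 had 0.83 and -0.69, not called in either, with a called difference of 1.52 (adjusted p = 0.0371). Efna5 fell in luminal cells (-1.23, SE 0.25). Slit3, Unc5c, Sema3c, Nrp1 and Ephb2 were not called in either cell type, and since the group was picked from the data no test of it as a set was made.

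Basal control replicate 3 stood apart from the other basal controls: Krt5 was at 7270 CPM against 2390 and 2570, Esr1 at 71.6 against 10.6 and 4.56, and Tspan8 at 9.98 against 27.3 and 36.6. On the second principal component, with 11.5% of the variance, it lay at -30.5, beside basal knockout-labelled libraries at -27.4, -0.829 and -30.5 and away from the other basal controls at 28 and 47, and luminal control replicate 3 at -17, beside luminal knockout-labelled libraries at -11.3, -23.6 and -53.7 and away from the other luminal controls at 45.2 and 74.7. On the third principal component, with 7.55% of the variance, it lay at -59.0 and luminal control replicate 3 at -54.2, while the other libraries lay between -17.5 and 42.0. Bpifa2 also took 0.0113% to 0.342% of counts in basal libraries. Of the 32 tested genes within 1 Mb of agouti and the 8 near Fmn2, 0 were called in either cell type, and of the 2 near Foxp1 also 0. Of the 13 near Csn2, 2 were called in basal (Csn1s1, Smr3a) and 3 in luminal cells (Csn1s1, Smr3a and Prol1, the last named after its values were seen).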
